A study of Homo sapiens with 13 samples.

How the data were processed

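RNA from CP-A hTERT, an immortalised human line of Barrett's oesophagus (columnar mucosa in place of the squamous lining), was measured on 13 Affymetrix HG-U133 Plus 2.0 arrays. Per the labels' protocols, flasks were exposed for 15 min to medium at pH 4.5 alone (acid), with a mixture of primary bile acids (bile mix) or with deoxycholic acid (DCA), a secondary bile acid. They were then washed, given normal medium and lysed at 2 h or 6 h. Control flasks had their medium replaced. The protocol names a concentration of 100 µM in a sentence that covers the primary bile acids and DCA, and does not settle whether it applies to each acid, to the mixture or to DCA. Groups came from the sample titles, with 2 arrays each for control, acid 2 h, acid 6 h, bile mix 2 h, DCA 2 h and DCA 6 h, and 1 array for bile mix 6 h, whose second replicate was not analysed here. Nothing in the labels says that the arrays of a group came from more than 1 flask per day, so the p-values measure the spread between these arrays.

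The deposited values were linear array intensity, 1 value per probe set and array, already summarised from the probes. The software, background method and detection calls were not given in the sources used here. From the values, every array had a 2% trimmed mean between 100.01 and 100.02, so each had been scaled to a common level. The median intensity lay between 12.1 and 22.0. Most probe sets therefore lay low on the scale. Of 54675 probe sets, 62 were controls. Among the other 54613, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none. Symbols were matched by Entrez identifier to a RefSeq gene table (assembly GRCh38.p14, used for names only) for 41037 probe sets, and none changed. Array files name no genome build, so no coordinates are given.

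Intensities were used as log2(intensity + 16), which understates the change of dim genes. A gene was represented by its probe set of highest mean, and genes under the 40th percentile of all non-control probe sets were left out, which kept 13942 genes. One mean per group was fitted over all 13 arrays with limma 3.58.1 in R 4.3.3 (6 residual degrees of freedom), followed by empirical Bayes moderation and Benjamini-Hochberg adjustment within each of 15 comparisons, with adjusted p under 0.05 as the threshold. The lone bile mix 6 h array was assumed to vary like the other groups. Changes are log2 differences with their standard error (SE). A group's intensity is a mean ± SD. The authors' design compares each exposure with control "2 x 2", so genes at least 2-fold apart in all 4 treated-control pairs were counted as well. Figures were drawn with matplotlib 3.10.9.

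The 24 gene lists, fixed before the data were examined, covered immediate early genes, the integrated stress response, endoplasmic reticulum (ER) chaperones, heat shock proteins, NRF2 targets, NF-kappaB and inflammatory genes, p53 targets, cholesterol synthesis, bile acid handling, columnar and intestinal markers, squamous markers, G1/S and replication, G2/M, EGFR ligands and ERK feedback, hypoxia and glycolysis, metallothioneins, interferon-stimulated genes, TGF-beta response, pH regulation, autophagy and lysosome, apoptosis regulators, fibroblast markers, leukocyte and endothelial markers, and ribosomal proteins. Of their 594 genes, 483 were among the genes tested. Each list was tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the lists within a comparison. At the preset correlation 81 list results passed. None of the 81 passed with an estimated correlation, and 21 passed with fry. List results below are from camera at the preset correlation unless another test is named.

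The named genes were fixed by rule. Against control, up to 12 rises and 12 falls of largest change were taken (6 each for bile mix 6 h) among genes past the threshold with all exposed arrays outside the control range. For other comparisons up to 8 per direction were taken. Where fewer than 5 genes passed, the 5 per direction with the smallest p were taken. Up to 4 called members were taken per list described, or, with none called, the 2 of largest change. FOS, EGR1, ATF3, DDIT3, CXCL8, PTGS2, MYC, HMOX1, CDKN1A, CDX2, KRT20 and MUC5AC were always reported.

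The replicate numbers 1 and 2 recur in each group, and the series design places the duplicates on separate days. Deviations from the group means correlated between same-numbered arrays across genes in all 15 pairs of groups, from 0.17 to 0.71, and the first principal component (28.5% of the variance) separated the numbers. The numbers were therefore taken to pair the arrays. The fit without the number as a block, fixed in advance, remained the main one, and the value with a replicate block is printed where it changes the call of a gene named there or moves a count over all genes by over 1.5 times. Leaving out 1 array from the fit without the block leaves the numbers uneven, so list medians within each number were added after those values were seen. Per the file headers, the arrays were run on 3 scan days. Day 1 held the 4 DCA arrays and no others, day 2 the controls and the bile mix arrays numbered 1, and day 3 the acid arrays and bile mix 2 h replicate 2. DCA and scan day cannot be told apart in any comparison of DCA with another group. Acid and bile mix comparisons were refitted with scan day as a block and within a day. The series text speaks of controls at the relevant times, but per the file headers both controls are 2 h controls, so each 6 h exposure was set against 2 h controls.

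The fit was tested on simulated data with the real gene means and replicate effects. Each gene had the same spread in all groups, taken from the real arrays. Each of 5 rounds held 13942 genes, 200 of them changed. For DCA 2 h versus control the fit called 5.2% of genes changed 2-fold, 77.6% changed 4-fold and 96% changed 8-fold, with 0 false calls. With the replicate block these were 35.2%, 99.6% and 100%, with 52 false calls over the 5 rounds. The 52 stand beside 88, 249, 250 and 250 right calls at 2-fold, 4-fold, 8-fold and 16-fold, out of 250 each. An adjusted p under 0.05 allows for some false calls among those made. For DCA versus acid over both times it called 40.8% at 2-fold and 94.8% at 4-fold, with 3 false calls. With the replicate block, a list shifted by 1 log2 unit at DCA 6 h was found in 5 of 5 rounds, and 0 other lists were called. The main list results come from the fit without the block, for which lists were not simulated. The simulated noise was drawn independently for each gene, so apart from the replicate effect members of a list were not correlated. These rounds therefore do not show how often lists of correlated genes would be called. In the real data 1917 genes were at least 2-fold apart between the DCA 2 h arrays, against 979 between the controls. With an equal spread in all groups, the rounds do not show how often DCA comparisons would give false calls. With 2 arrays per group the number of arrays limits the precision. The median half-width of a 95% interval was 0.71 log2 units for a comparison of 2 groups of 2.

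Alternatives fixed in advance were quantile normalization, median centring, no filter, a filter at the 60th percentile, the median over probe sets, every probe set tested on its own, pseudocounts of 1 and 64, only the groups compared, the replicate block, trend and robust moderation, scan day as a block, and each array left out. Others were added after seeing the data. These were scan day and replicate number together, the arrays of 1 scan day only, the 3' to 5' ratio of the actin control probe sets as a covariate, the replicate block without DCA 2 h replicate 2, and the replicate block with quantile normalization.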

Results

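The series asked which genes acid and bile change in a Barrett's oesophagus cell line after a short exposure that mimics reflux. CP-A hTERT cells were sampled 2 h or 6 h after 15 min at pH 4.5, alone, with mixed primary bile acids or with deoxycholic acid (DCA). The 13 arrays were 2 controls, 2 each for acid 2 h, acid 6 h, bile mix 2 h, DCA 2 h and DCA 6 h, and 1 for bile mix 6 h. The arrays of a group correlated at 0.93 to 0.97 over 13942 genes. DCA 2 h was lowest at 0.93, with 1917 genes at least 2-fold apart between its arrays, against 979 between the controls. The log2 ratio of the 3' to the 5' actin control probe set, a sign of RNA quality, was 0.61 and 1.08 in DCA 2 h and 0.36 and 0.57 in DCA 6 h. It was 0.35 and 0.25 in the controls and between 0.04 and 0.16 in the acid arrays.

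The first question was what DCA did at 2 h. DDIT3, the pro-apoptotic factor CHOP of the unfolded protein response, went from 60.5 ± 30.0 in control to 3965 ± 2052 (SD, n = 2 each), a log2 change of 5.66 ± 0.65 (SE; limma adjusted p = 0.019). ATF3 rose by 4.26 ± 0.48, from 226.5 ± 72.6 to 5085 ± 3315. ZNF165 rose by 4.88, next to DDIT3 in size. The chemokine genes CXCL2 and CXCL3 rose by 4.39 and 2.83, the cytokine gene IL6 by 2.58, and the AP-1 and zinc finger factors FOSB and EGR1 by 4.13 and 3.60. HERPUD1 and SDF2L1, which act in ER protein quality control, rose by 3.39 and 2.23, and EIF2AK3, the ER stress kinase PERK, by 1.83. The other called genes were PNRC1 (2.97), ZNF555 (2.14), SELENOK (2.13), MIS12 (1.98) and PIGA (1.98). EIF2AK3, SELENOK, MIS12 and PIGA fell outside the naming rule and were named after their values were seen.

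In this comparison 16 genes rose and 0 fell. With the replicate block 80 rose and 0 fell, the 16 among them. There were 0 calls with the actin ratio as a covariate, 0 with a pseudocount of 1 and 1 with only the 4 arrays compared. With the ratio the median change of the 16 went from 2.90 to 2.01 and its median SE from 0.42 to 0.50. At an unadjusted p under 0.05 there were 1280 genes (2037 with the replicate block), where evenly spread p-values would give about 697.1. The fit without the block leaves the difference between the numbers in its spread, so 697.1 is no exact mark for it. All 29 measured immediate early genes were higher after DCA at 2 h, by a median of 1.47, and by 0.69 and 2.30 within numbers 1 and 2. The number 2 array, DCA 2 h replicate 2, had the highest actin ratio of all arrays (1.08). Of these genes 3 rose over all genes and 20 adjusted over the list alone (adjusted p = 3.4e-19, camera; adjusted p = 0.26 with an estimated correlation and 0.031 by fry). All 27 NF-kappaB and inflammatory genes were higher, by a median of 0.89 (0.58 and 1.26 within the numbers), with 3 called over all genes and 14 adjusted over the list alone (adjusted p = 1.2e-16; 0.25 as an adjusted p with an estimated correlation). Of 23 ER chaperone genes 19 were higher, by a median of 0.89 (0.89 and 0.87 within the numbers), with 2 called and 10 adjusted over the list alone (adjusted p = 3.9e-09; adjusted p = 0.28 with an estimated correlation). Of 29 integrated stress response genes 22 were higher (median 0.28), with DDIT3 and ATF3 called and 8 adjusted over the list alone (adjusted p = 0.00025; adjusted p = 0.56 with an estimated correlation). This median turned to -0.47 without DCA 2 h replicate 1 (adjusted p = 0.43) and to -0.32 without control replicate 2 (0.20), which leaves the numbers uneven. Within numbers 1 and 2 it was 0.25 and 0.55. The heat shock list had a median of 0.49 (adjusted p = 0.00077; adjusted p = 0.63 with an estimated correlation), and its largest member HSPA6, at 5.70 ± 1.10, did not pass without the replicate block (adjusted p = 0.11; 0.027 with it). The heat shock median was -0.017 without DCA 2 h replicate 2 (adjusted p = 0.49), 0.30 without control replicate 1 (0.054), and -0.20 with the actin ratio as a covariate. Within numbers 1 and 2 it was 0.095 and 0.89. The EGFR ligand and ERK feedback list had a median of 0.47 (adjusted p = 0.035; adjusted p = 0.26 with an estimated correlation), with 0 genes called and 2 adjusted over the list alone. It did not pass without DCA 2 h replicate 1 (adjusted p = 0.066), DCA 2 h replicate 2 (0.14) or control replicate 2 (0.083). HBEGF stood at 1.17 ± 0.22 (adjusted p = 0.097; 0.033 with the replicate block) and DUSP5 at 1.30.

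Other genes reported in every comparison did not pass in DCA 2 h without the block. CXCL8, the gene of interleukin-8, was at 2.57 ± 0.50 (adjusted p = 0.11; 0.0014 with the replicate block). HMOX1, the haem oxygenase gene, was at 5.40 ± 1.19 (adjusted p = 0.18; 0.030 with the block). PTGS2 was at 1.16, FOS at 0.88, CDKN1A at 0.58, KRT20 at 0.48, MYC at 0.29 and MUC5AC at 0.09. INSIG1 and HMGCS1 of cholesterol synthesis were at 3.30 and 2.25 and passed with the block (adjusted p = 0.0014 and 0.027), while the median of that list was 0.12. KRT20 and MUC5AC were dim, with group means of 11.8 to 31.4 and 3.48 to 20.3, and both CDX2 probe sets were below the filter, at or under 7.64 on every array. Without DCA 2 h replicate 2 there was 1 gene called, without replicate 1 there were 156, and without either control 0. There were 4 without either acid 6 h array and 9 without either bile mix 2 h array.

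**Figure D1:**
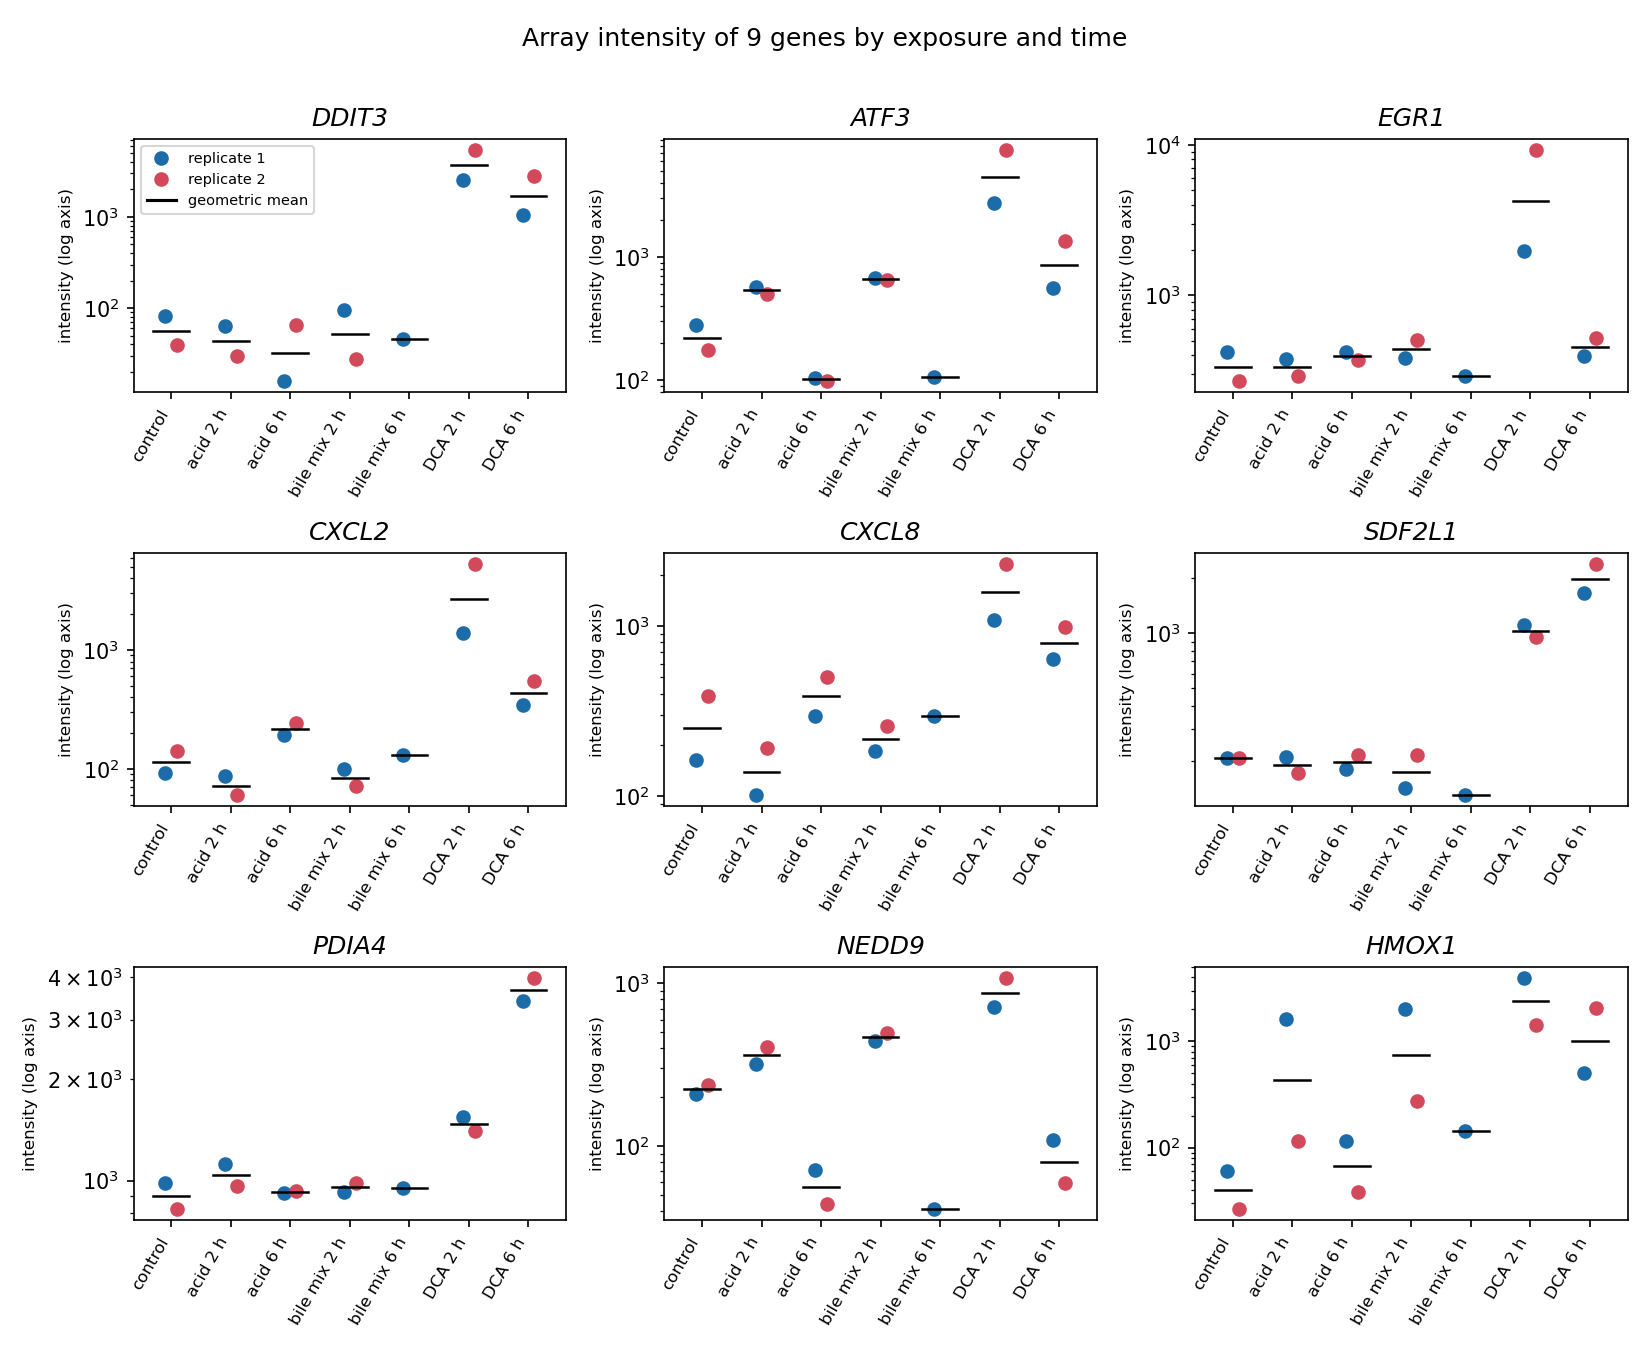
Intensity on each array (log axis) of 9 genes by exposure and time, with points coloured by replicate number and bars at the geometric mean of a group (1 array for bile mix 6 h). Each gene is shown by its probe set of highest mean. DDIT3, ATF3, EGR1, CXCL2 and CXCL8 were highest in DCA 2 h, SDF2L1 and PDIA4 were highest in DCA 6 h, and NEDD9 was lower at 6 h than at 2 h in each exposure.

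At 6 h after DCA 5 of the 10 called genes were members of the ER chaperone list. SDF2L1 rose from 207.0 ± 0.3 to 2023 ± 524, a log2 change of 3.17 ± 0.28 (limma adjusted p = 0.0036). CRELD2 rose by 2.79 ± 0.34, PDIA4, a protein disulphide isomerase, by 2.01 ± 0.23, MANF by 1.97 ± 0.25 and DNAJC3 by 1.71 ± 0.23. DDIT3 remained high at 1925 ± 1241, a change of 4.56 ± 0.65 (adjusted p = 0.042). The others were TMEM50B (2.43), SELENOK (2.06), OLR1, which encodes an oxidised lipoprotein receptor (1.84), and SLC35B1 (1.64). In total 10 genes rose and 0 fell, and with the replicate block 37 rose and 0 fell, the 10 among them. The count was 5 with the actin ratio as a covariate, 1 with a pseudocount of 1 and 2 with only the 4 arrays compared. With the ratio the median change of the 10 went from 2.04 to 1.94. There were 1042 genes at an unadjusted p under 0.05.

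All 23 ER chaperone genes were higher at 6 h after DCA, by a median of 1.45. Of these 5 rose over all genes and 19 adjusted over the list alone (adjusted p = 6.6e-29, camera; 0.0055 by fry). This list's adjusted p with an estimated correlation was 0.087, and 0.038 with the replicate block. The integrated stress response list (median 0.62, adjusted p = 2.5e-05; adjusted p = 0.58 with an estimated correlation) had DDIT3 called, and its median turned to -0.13 without control replicate 2 (adjusted p = 0.15) and was -0.055 and 1.40 within numbers 1 and 2. The NRF2 target list (median 0.54, adjusted p = 1.4e-06), the NF-kappaB list (median 0.50, adjusted p = 5.6e-06) and the heat shock list (median 0.45, adjusted p = 8.1e-05) had 0 genes called, and their adjusted p with an estimated correlation was 0.42, 0.42 and 0.63. Within numbers 1 and 2 the medians were 0.23 and 0.93 for NRF2, 0.11 and 0.97 for NF-kappaB and 0.45 and 0.62 for heat shock. The first 2 rises thus lay mainly in number 2. HMOX1 was at 4.19, AKR1C1 at 1.69, CXCL2 at 1.80, CXCL8 at 1.59 (adjusted p = 0.49; 0.022 with the replicate block), HSPA6 at 4.71 and CRYAB at 2.32. The immediate early list did not pass at 6 h (median 0.16, adjusted p = 0.94). EGR1 was at 0.42, ATF3 at 1.90, FOS at -1.5, PTGS2 at -0.11, MYC at -0.06, CDKN1A at 0.42, KRT20 at 0.63 and MUC5AC at -0.43. The G2/M list was lower (median -0.83, adjusted p = 0.00041; adjusted p = 0.88 with an estimated correlation), with TOP2A at -1.89 and HMMR at -1.72, and the TGF-beta list had a median of -0.45 (adjusted p = 0.00086; adjusted p = 0.42 with an estimated correlation), with CCN2 at -1.62 and FN1 at -1.48. None of these 2 lists' genes passed on its own. The G2/M median turned to 0.26 without DCA 6 h replicate 1 (adjusted p = 0.95) and to 0.16 without control replicate 2 (0.86), which leaves the numbers uneven. Within numbers 1 and 2 it was -1.01 and -0.73, lower in both. The TGF-beta list did not pass without DCA 6 h replicate 2 (-0.19, adjusted p = 0.083) or control replicate 1 (-0.34, 0.051). Both controls are marked as 2 h controls, so time and exposure are not separated here. Without DCA 6 h replicate 2, or without either control, 0 genes were called. Counts were 4 to 6 without 1 array of DCA 2 h, acid or bile mix 2 h.

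Acid alone changed no gene past the threshold at either time. At 2 h limma called 0 genes, with and without the replicate block, and 180 genes had an unadjusted p under 0.05 (372 with the block). Evenly spread p-values would give 697.1, but the fit without the block leaves the difference between the numbers in its spread. The low count is therefore no evidence that acid changed nothing. The smallest p values among higher genes belonged to CRIP1 (1.17 ± 0.28), ARHGEF17 (1.20), RRAD (1.69), TEX13B (1.00) and PADI3 (0.84), and among lower genes to CD79B (-0.98), LST1 (-1.13), NFYC-AS1 (-0.78), PCSK1N (-1.06) and SNRPF-DT (-0.91), none of which passed. HMOX1 was at 3.03 ± 1.19 and ATF3 at 1.22 ± 0.48, and FOS, EGR1, DDIT3, CDKN1A, KRT20 and MUC5AC lay between -0.29 and 0.06. CXCL8 was at -0.79, PTGS2 at -0.56 and MYC at -0.39. The EGFR ligand and ERK feedback list was lower (median -0.25, 21 of 23 members, adjusted p = 0.014; adjusted p = 0.26 with an estimated correlation), with ERRFI1 at -0.85 and EREG at -0.50 and 0 members called. Without control replicate 1 its median was -0.17 (adjusted p = 0.11). With scan day and replicate blocks it was -0.019 (adjusted p = 0.73), and limma called 0 genes.

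At 6 h after acid limma again called 0 genes with and without either block, and 303 had an unadjusted p under 0.05. NEDD9, a scaffold of focal adhesions, was at -1.73 ± 0.32 and PTGS2 at -1.62 ± 0.33, neither past the threshold, nor were FLJ40288 (-1.06), SRGAP3 (-1.08) and SRSF5 (-1.24). ATF3 was at -1.01, FOS at -0.96, CXCL8 at 0.58, HMOX1 at 0.58, DDIT3 at -0.53, MUC5AC at 0.47, MYC at -0.31, CDKN1A at -0.27, EGR1 at 0.23 and KRT20 at 0.09. All 28 G2/M genes were lower (median -0.62, adjusted p = 0.0033) and all 27 G1/S and replication genes higher (median 0.46, adjusted p = 0.0024), with HMMR at -1.45, NEK2 at -1.33, MCM6 at 1.14 and MCM5 at 1.11. The heat shock list was higher (median 0.42, adjusted p = 0.0033), with HSPA6 at 1.72 and HSPH1 at 0.79. The immediate early list was lower (median -0.31, adjusted p = 0.0024), with FOSB at -1.31. Each of these 4 lists had 0 genes called, also adjusted over the list alone, and an adjusted p of 0.81 with an estimated correlation. Leaving out 1 array, which makes the numbers uneven, turned the cell cycle medians. The G2/M median was 0.52 without acid 6 h replicate 1 (adjusted p = 0.027) and 0.29 without control replicate 2 (0.43). The G1/S median was -0.24 without control replicate 1 (0.18) and 0.22 without acid 6 h replicate 2 (0.37). Within numbers 1 and 2 the G2/M median was -0.86 and -0.42, lower in both, and the G1/S median 1.05 and 0.065, so the G1/S change lay mainly in number 1. Without control replicate 1 the heat shock and immediate early lists did not pass either (0.18 and -0.19, adjusted p = 0.18 each). Bile mix 2 h alone links the scan days of acid and control, with number 1 on the control day and number 2 on the acid day. A scan day block without the numbers therefore takes up the difference between its numbers (1.66 for G2/M and 1.79 for G1/S), and its medians do not show an effect of the day. With scan day and replicate blocks the G2/M median was -0.37, the G1/S median -0.0025, the heat shock median 0.35 and the immediate early median 0.13.

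The bile mix at 2 h gave 0 calls with limma, with and without the replicate or scan day block, and 137 genes at an unadjusted p under 0.05. Within scan day 2 bile mix 2 h has a single array, so a fit to that day alone (1 call, HMOX1) says little. Over all arrays HMOX1 was at 3.77 ± 1.19 and ATF3 at 1.51 ± 0.48. MYC was at -0.69, EGR1 at 0.37, CXCL8 at -0.20, DDIT3 at -0.07, PTGS2 at -0.06, CDKN1A at 0.07, MUC5AC at 0.06, KRT20 at -0.02 and FOS at 0.01. The smallest p values belonged to ARHGEF17 (1.13), FTCD (0.92), SPN (1.57), RRAD (1.51) and SLC38A2-AS1 (1.07) among higher genes and to PTCRA (-1.35), GRM8 (-0.84), NFYC-AS1 (-0.87), CIMAP1A (-1.08) and CYP2A6 (-0.93) among lower ones, none past the threshold. No list passed. The bile acid handling list, which holds sensors and transporters of bile acids, had 9 measured members and a median of 0.12 (adjusted p = 0.51), with CYP3A4 at 0.90.

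The single bile mix 6 h array gave 0 calls with limma, with the replicate block or scan day block too, and 426 genes at an unadjusted p under 0.05. All 28 G2/M genes were lower by a median of -1.79 (adjusted p = 1e-12; adjusted p = 0.85 with an estimated correlation), with HMMR at -2.89 and NEK2 at -2.55. With the replicate block the median was -0.86. This array is numbered 1, and arrays numbered 1 had lower G2/M levels than those numbered 2 in each of the 6 groups with both. The immediate early list had a median of -0.35 (adjusted p = 0.00012; adjusted p = 0.85 with an estimated correlation), with FOS at -1.67 and JUN at -1.44. NEDD9 stood at -2.07 ± 0.40, UBOX5 at -1.82, NDOR1 at -1.94, GSE1 at -1.57 and PABPN1P1 at -1.53. NKX6-2 was at 1.5, CDH24 at 1.38, BANP at 1.29, KIF19 at 1.77 and PECAM1 at 1.14. PTGS2 was at -1.69, HMOX1 at 1.48, ATF3 at -0.96, KRT20 at 0.49, CDKN1A at -0.28, DDIT3 at -0.26, CXCL8 at 0.21, EGR1 at -0.20, MYC at -0.17 and MUC5AC at 0.09. None of these genes passed, and the controls are marked 2 h. Both controls and this array share a scan day, so a day block cannot move these medians.

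**Figure D2:**
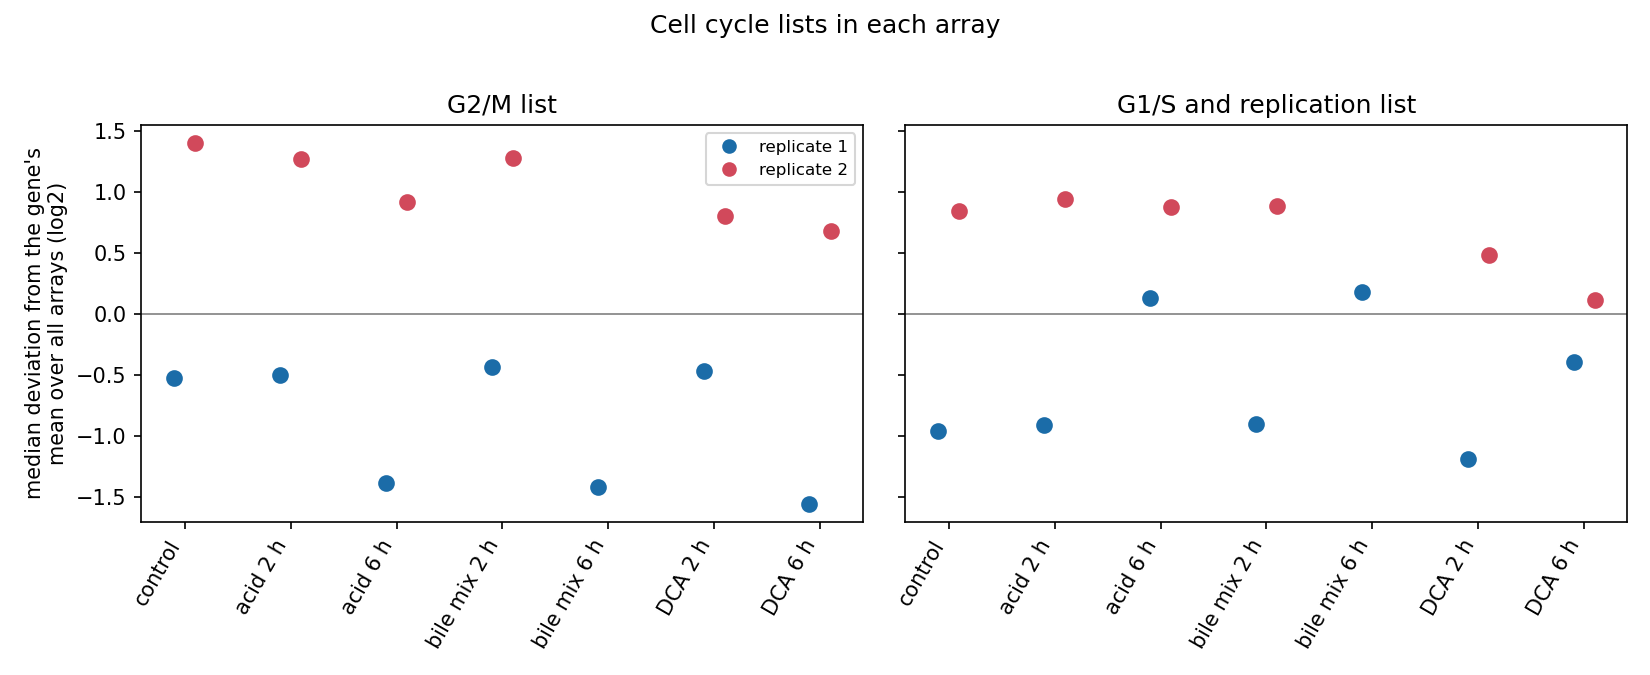
Median deviation of the G2/M list (left) and the G1/S and replication list (right) from each gene's mean over all arrays, for each array, coloured by replicate number. Bile mix 6 h has 1 array. The arrays numbered 2 were higher than those numbered 1 in both lists in each of the 6 groups with 2 arrays.

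**Figure D3:**
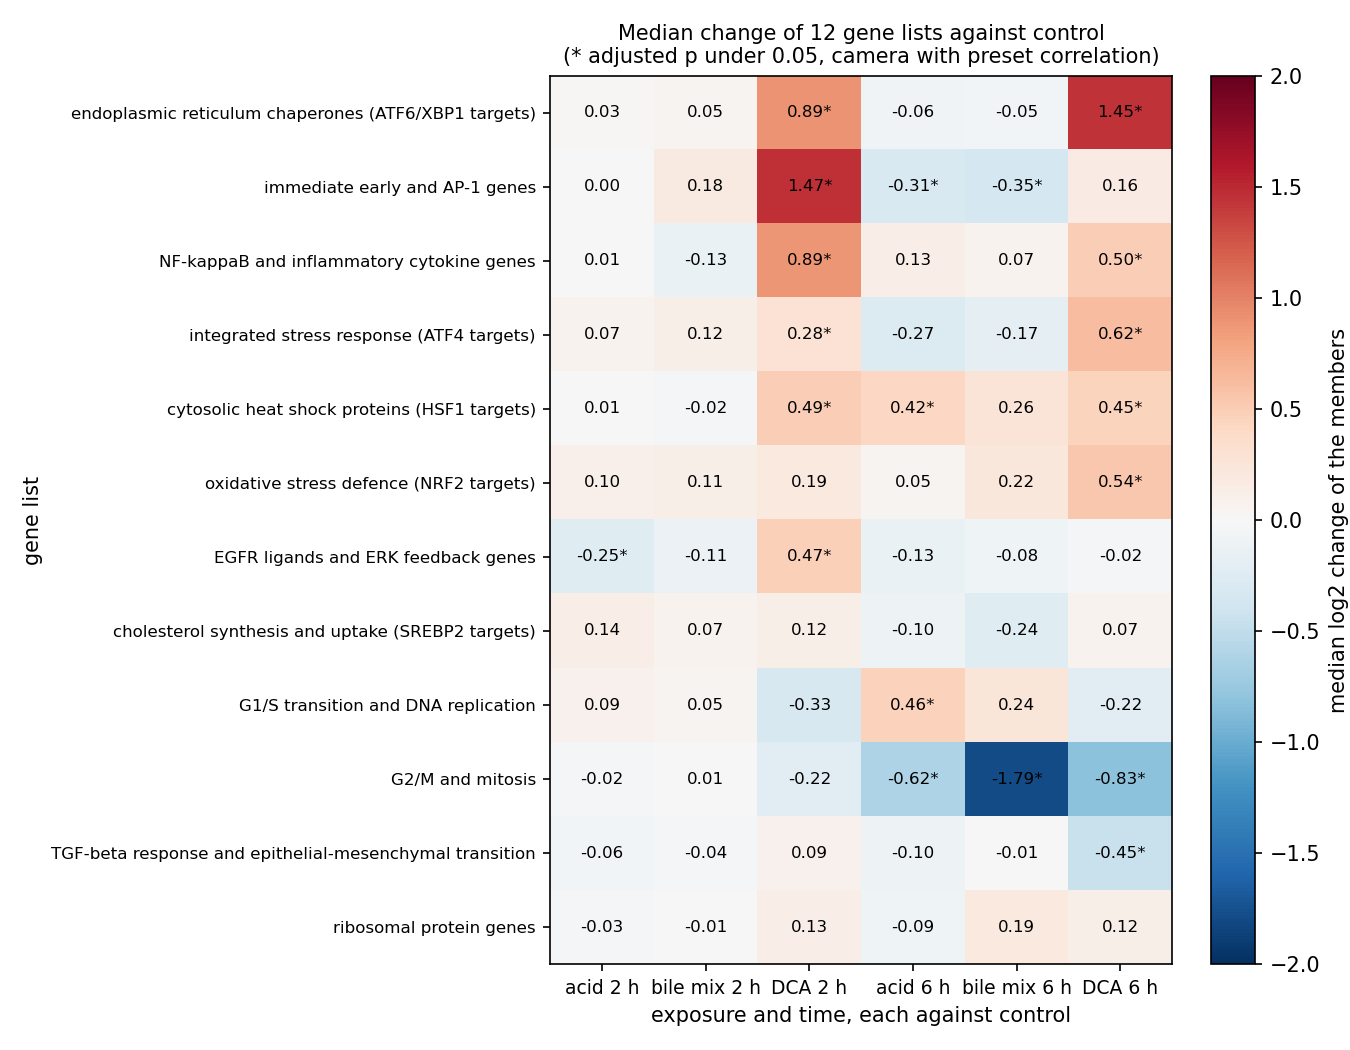
Median log2 change of the measured members of 12 gene lists (rows) for each exposure and time against control (columns), with colour on a scale from -2 to 2. ER chaperones stood at 0.89 and 1.45 after DCA at 2 h and 6 h and between -0.06 and 0.05 after acid and bile mix. Within numbers 1 and 2 the ER median in acid 6 h was -0.29 and 0.03. The bile mix 6 h array, numbered 1, deviated by a median of -0.40 from each gene's mean over all arrays, against -0.06 in control 1.

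Counting genes at least 2-fold apart in all 4 exposed-control pairs, as in the design of the series, gave 102 higher and 3 lower in DCA 2 h and 59 higher and 9 lower in DCA 6 h. Acid gave 5 genes in all at 2 h and 7 at 6 h, and bile mix 2 h gave 5. For 2 arrays against 2, chance leaves the groups apart in 1 of 3 genes. Dividing the same 4 arrays by replicate number instead gave 321 genes for DCA 2 h, 148 for DCA 6 h, 445 for acid 2 h, 187 for acid 6 h and 436 for bile mix 2 h. The third division, which crosses both, gave 4 for DCA 2 h, 12 for DCA 6 h, 1 for acid 2 h, 3 for acid 6 h and 1 for bile mix 2 h. The bile mix 6 h array had 149 such genes, over 2 pairs.

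The exposures were then set against one another at matched times. DCA and bile mix shared the pH and the exposure time, and whether they shared a concentration is not settled by the labels. At 2 h DCA exceeded acid in 14 genes and was below it in 0 (102 and 3 with the replicate block). Both the actin ratio as a covariate and a pseudocount of 1 left 0 calls, and only the 4 arrays compared left 1. With the ratio the median change of the 14 went from 2.78 to 1.55 and its median SE from 0.41 to 0.62. The immediate early median went from 1.47 to 0.035 with the actin ratio. DDIT3 was 5.95 ± 0.65 higher (limma adjusted p = 0.014), CXCL2 4.95, NFKBIZ, an inducible regulator of NF-kappaB, 4.21, EGR1 3.62, FOSB 3.52, CXCL8 3.36, CXCL3 2.91 and TNFAIP3 2.66. Of 27 NF-kappaB and inflammatory genes 24 were higher (median 1.21, adjusted p = 1.9e-16; adjusted p = 0.13 with an estimated correlation), with 5 called and 14 adjusted over the list alone. The p53 target list had a median of 0.38 (adjusted p = 0.040; adjusted p = 0.19 with an estimated correlation), with PMAIP1 at 1.75 (adjusted p = 0.22; 0.025 with the replicate block) and 0 genes called. It did not pass without either DCA 2 h array, either DCA 6 h array or acid 2 h replicate 1 (adjusted p from 0.052 to 0.10). ATF3 missed the threshold at 3.04 (adjusted p = 0.053; 0.013 with the replicate block). Without either acid 2 h array 0 genes were called, without DCA 2 h replicate 2 there was 1, and without DCA 2 h replicate 1 there were 197. There were 3 without any 1 of the DCA 6 h or bile mix 2 h arrays, 2 without either acid 6 h array and 6 without either control.

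DCA differed from the bile mix at 2 h in the same direction. This comparison uses the same DCA 2 h arrays as that with acid, so it is no independent support. Here too DCA and scan day cannot be told apart. DCA was higher in 6 genes and lower in 0 (57 and 0 with the replicate block). These were DDIT3 (5.72 ± 0.65, limma adjusted p = 0.015), CXCL2 (4.77), NFKBIZ (4.03), SDF2L1 (2.45), MIS12 (2.01) and EIF2AK3 (1.81). The unadjusted 95% interval of the difference was 4.29 to 7.16 for DDIT3, 2.01 to 4.46 for EGR1 and 1.68 to 3.87 for CXCL8, the latter 2 short of the adjusted threshold without the replicate block (adjusted p = 0.096 and 0.11) and past it with the block (0.025 and 0.00093). No gene was called with the actin ratio as a covariate, with a pseudocount of 1, or with only the 4 arrays compared. With the ratio the median change of the 6 went from 3.24 to 2.66 and its median SE from 0.40 to 0.49. Without either bile mix 2 h array 0 genes were called, without DCA 2 h replicate 2 there was 1, and without DCA 2 h replicate 1 there were 126. There were 3 without any 1 of the DCA 6 h, acid or control arrays. For bile mix against acid at 2 h limma called 0 genes with and without either block, 122 had an unadjusted p under 0.05, and no list passed. The 95% intervals of this difference were -1.21 to 1.66 for DDIT3, -0.77 to 1.35 for ATF3, -0.51 to 1.68 for CXCL8 and -1.88 to 3.36 for HMOX1. They come from the fit without the block, which leaves the difference between the numbers in its spread. On them, differences of over 2-fold in either direction are not excluded for DDIT3 and HMOX1. Against same-number controls HMOX1 was at 4.758 and 2.784 in bile mix and 4.436 and 1.625 in acid, higher in bile mix in both numbers. The smallest p values were those of WWC3 (1.08), CST5 (1.06), GRPR (0.90), SLC38A2-AS1 (1.03) and PECAM1 (0.73) among higher genes and of TRPM2 (-0.97), MEDAG (-0.92), PTCRA (-1.31), PLEC (-0.92) and UNC93B1 (-0.92) among lower ones, none past the threshold.

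At 6 h DCA exceeded acid in 10 genes and was below it in 0 (46 and 0 with the replicate block). DDIT3 was 5.08 ± 0.65 higher (limma adjusted p = 0.020), HERPUD1 3.55, SDF2L1 3.23, CRELD2 2.97, TMEM50B 2.33, SELENOK 2.21, MANF 2.01 and PDIA4 1.97. All 23 ER chaperone genes were higher (median 1.64, adjusted p = 1.4e-33; adjusted p = 0.060 with an estimated correlation, and 0.027 with the replicate block), with 6 called and 20 adjusted over the list alone. Both groups were taken at 6 h, so the marking of the controls does not enter. The integrated stress response list had a median of 0.98 (adjusted p = 4e-08; adjusted p = 0.75 with an estimated correlation). Without DCA 6 h replicate 2, or without either acid 6 h array, 0 genes were called. The actin ratio as a covariate left 0, with a median change of 2.41 for the 10 against 2.27 without it and a median SE of 0.35 against 0.28, and a pseudocount of 1 left 1.

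Over both times DCA exceeded acid in 67 genes and was below it in 4 (184 and 25 with the replicate block, the 71 among them). DDIT3 was 5.51 ± 0.46 higher (limma adjusted p = 0.00095), ZNF165 4.06, HERPUD1 3.36, ATF3 2.97, CXCL2 2.96, SDF2L1 2.79, ZSCAN12P1 2.66 and FOSB 2.50. The lower genes were PLEC (-1.35), which encodes the cytolinker plectin, TGOLN2 (-1.14), UNC93B1 (-1.03) and MOV10 (-0.99). Of 23 ER chaperone genes 11 were called, 18 adjusted over the list alone (median 1.20, adjusted p = 3.4e-23; adjusted p = 0.15 with an estimated correlation). Among inflammatory genes 6 of 27 were called, CXCL2, NFKBIZ (2.45), CXCL8 (2.19) and IL6 (1.84) most strongly, and PTGS2, the cyclooxygenase-2 gene, was 1.62 ± 0.24 higher (adjusted p = 0.020). Among integrated stress response genes 5 of 29 were called, with PPP1R15A at 2.39 and CHAC1 at 2.09 after DDIT3 and ATF3. STARD4, a sterol carrier, was 1.96 higher and HBEGF 1.00 higher. The G1/S and replication list was lower (median -0.52, adjusted p = 0.00061; adjusted p = 0.76 with an estimated correlation) with 0 genes called. It did not pass without DCA 2 h replicate 1 (-0.11, adjusted p = 0.27), DCA 6 h replicate 1 (-0.36, 0.052) or acid 2 h replicate 2 (-0.04, 0.35), which leaves the numbers uneven. Within numbers 1 and 2 it was -0.25 and -0.50 at 2 h and -0.67 and -0.77 at 6 h. The ribosomal protein list had a median of 0.21 (adjusted p = 0.035; adjusted p = 0.76 with an estimated correlation), which turned to -0.05 with quantile normalization. It did not pass without any 1 of DCA 2 h replicates 1 and 2, DCA 6 h replicate 1, acid 2 h replicate 2 and acid 6 h replicate 2 (adjusted p from 0.053 to 0.24). DCA arrays had their own scan day, so exposure and day cannot be told apart here, and with the actin ratio as a covariate 0 genes were called. The median change of the 71 then went from 1.49 to 0.96 and its median SE from 0.24 to 0.45. For the ER chaperone list the median was 1.20 without the ratio and 1.21 with it, while the median SE went from 0.24 to 0.47, so the calls of this list ended through lost precision. With a pseudocount of 1 there were 16 and with only the 8 arrays compared 40. The count was 22 without DCA 2 h replicate 2, 169 without DCA 2 h replicate 1, 12 without DCA 6 h replicate 2 and 154 without DCA 6 h replicate 1. It was 19 and 16 without acid 2 h replicates 1 and 2, 16 and 17 without acid 6 h replicates 1 and 2, and 44 without either control.

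Time was compared within an exposure, where DCA arrays share a scan day and acid arrays share another. From 2 h to 6 h after DCA, NEDD9 fell from 895.8 ± 259.1 to 83.8 ± 34.7, a log2 change of -3.21 ± 0.32 (limma adjusted p = 0.013), the only gene past the threshold. With the replicate block 6 genes rose and 32 fell, among them FOSB (-3.95), INSIG1 (-3.35), EGR1 (-3.19) and CXCL2 (-2.59). All 29 immediate early genes were lower at 6 h (median -1.31, adjusted p = 1.1e-20; adjusted p = 0.19 with an estimated correlation, 0.048 by fry), with 20 past the threshold adjusted over the list alone. Of 27 inflammatory genes 22 were lower (median -0.88, adjusted p = 7.9e-06; adjusted p = 0.33 with an estimated correlation), which did not pass without DCA 6 h replicate 1 (-0.67, adjusted p = 0.063). Of 23 ER chaperones 21 were higher (median 0.63, adjusted p = 4.1e-10; adjusted p = 0.22 with an estimated correlation), PDIA4 by 1.31. OLR1 (1.49), TMEM50B (1.66), YKT6 (1.37) and COBLL1 (1.46) were among the higher genes of smallest p, and TOX2 (-1.64), PER2 (-2.45) and RHOB (-2.32) among the lower. None of these 7, nor PDIA4, passed without the replicate block, and all 8 did with it (adjusted p from 0.019 to 0.045). NEDD9 did not pass with only the 4 DCA arrays (adjusted p = 0.25), without DCA 2 h replicate 2 (0.14) or without DCA 6 h replicate 2 (0.27), and its median over probe sets changed by -0.56 (0.64). There were 121 calls without DCA 2 h replicate 1, 2 without DCA 6 h replicate 1 and 0 without DCA 6 h replicate 2. The count was 0 with the actin ratio as a covariate (NEDD9 -3.18 ± 0.45), with a pseudocount of 1, and with only the 4 arrays compared.

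After acid, limma called 0 genes between 2 h and 6 h, with either block too, and 257 had an unadjusted p under 0.05. NEDD9 was at -2.38 ± 0.32, RRAD at -2.10, NFATC2 at -1.43, MED26 at -1.27 and ATF3 at -2.23. ND6 (1.02), GRPR (1.08), SMPD3 (1.07), STYK1 (1.39) and PECAM1 (0.80) had the smallest p among higher genes. The G2/M list was lower (median -0.62, adjusted p = 0.0026) and the integrated stress response (-0.31, adjusted p = 0.0049) and immediate early lists (-0.25, adjusted p = 0.0026) too, each at an adjusted p of 0.61 with an estimated correlation, and the G1/S list was higher (0.42, adjusted p = 0.0026; 0.61 likewise). Leaving out 1 acid array, which makes the numbers uneven, turned some of these medians. The G2/M median was 0.49 without acid 6 h replicate 1 (adjusted p = 0.015) and 0.25 without acid 2 h replicate 2 (0.36). Without acid 2 h replicate 1 the G1/S median was -0.42 (0.019) and the integrated stress response median 0.17 (0.92), and without acid 6 h replicate 2 they were 0.14 (0.52) and -0.11 (0.10). Within numbers 1 and 2 the G2/M median was -0.92 and -0.37, lower in both. The G1/S median was 1.06 and -0.06 and the integrated stress response median -0.73 and 0.02, so these 2 changes lay in number 1. All acid arrays share a scan day, so a day block cannot move these medians. The ER chaperone list was also lower (median -0.16) and the heat shock list higher (0.22). Both passed by camera (adjusted p = 0.014 and 0.017 with the scan day block) but not with an estimated correlation. Within numbers 1 and 2 the ER median was -0.33 and -0.0013 and the heat shock median 0.30 and 0.078. The hypoxia and glycolysis list was higher (median 0.22, adjusted p = 0.019; adjusted p = 0.59 with an estimated correlation) and the cholesterol synthesis list lower (median -0.17, adjusted p = 0.027; adjusted p = 0.61 with an estimated correlation). Neither passed without acid 6 h replicate 1 (0.10 and -0.06) or acid 2 h replicate 2 (0.18 and 0.083), and within numbers 1 and 2 they were 0.19 and 0.12 and -0.16 and -0.34. Over acid and DCA together NEDD9 (-2.79 ± 0.23, adjusted p = 0.0017) and FOSB (-2.94 ± 0.36, adjusted p = 0.045) fell and 0 genes rose, and with the replicate block 17 fell and 1, COBLL1 at 1.05, rose. The count was 1 without any 1 of the DCA 6 h, acid, control or bile mix 2 h arrays, and 13 without DCA 2 h replicate 1. The pH regulation list was higher at 6 h over both (median 0.15, adjusted p = 0.042; adjusted p = 0.36 with an estimated correlation), but not past the threshold without either DCA 6 h array, DCA 2 h replicate 2, acid 2 h replicate 1 or either acid 6 h array (adjusted p from 0.056 to 0.20).

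Whether the change from 2 h to 6 h differed between DCA and acid was tested as an interaction. No gene passed with or without either block, and 556 had an unadjusted p under 0.05. CXCL2 (-3.97 ± 0.73), DLX2 (-2.29), CCDC60 (-1.49), LOC114224 (-2.26) and ND6 (-1.61) had the smallest p among genes that moved down more after DCA, and OLR1 (1.66), PDIA4 (1.48), TMEM50B (1.67), KYNU (1.22) and MVD (1.60) among those that moved up more. As lists, ER chaperones moved up more after DCA (median 0.82, adjusted p = 4.8e-13) and immediate early (-1.09, adjusted p = 8.4e-12) and inflammatory genes (-0.97, adjusted p = 3.3e-07) moved down more. Their adjusted p with an estimated correlation was 0.26, 0.28 and 0.28. Leaving out DCA 2 h replicate 1 gave 8 calls.

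The remaining lists passed in no comparison with control. Their medians in DCA 2 h and DCA 6 h were 0.12 and 0.22 for columnar and intestinal markers (adjusted p = 0.22 and 0.067), 0.16 and 0.24 for squamous markers (0.64 and 0.057), and 0.29 and 0.01 for metallothioneins (0.52 and 0.53). They were 0.09 and -0.21 for interferon-stimulated genes (adjusted p = 0.85 and 0.34), 0.10 and 0.11 for autophagy and lysosome (0.78 and 0.67), and 0.18 and 0.15 for apoptosis regulators (0.35 and 0.68). For markers of other cell types the medians were -0.30 and 0.11 for fibroblasts (5 measured, adjusted p = 0.87 and 0.96) and 0.06 and 0.13 for leukocytes and endothelium (6 measured, adjusted p = 0.64 and 0.68).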

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

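Tests chosen only after the result was seen were those of scan day on the immediate early and ER lists, of the actin ratio on both lists (added after seeing the data, though for the ER list before that result was seen), of the ER list without DCA 2 h replicate 2, and of splits with the replicate block.

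The log2 ratio of the 3' to the 5' actin control probe set, which no comparison uses, was above both controls (0.35 and 0.25) in 5 arrays. These were DCA 2 h replicates 1 and 2 (0.61 and 1.08), DCA 6 h replicates 1 and 2 (0.36 and 0.57) and bile mix 2 h replicate 1 (0.41). In the time comparisons NEDD9 stood out between 2 h and 6 h after DCA (-3.21), and NEDD9 (-2.79) and FOSB (-2.94) over acid and DCA, each with an adjusted p under the threshold of 0.05. For DCA alone 0 calls were left with the median over probe sets or with only the DCA arrays. With the actin ratio as a covariate 0 calls were left in both comparisons. No group had 4 arrays, so no array was tested as an outlier.

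The pattern weighed here is the rise after DCA, in 2 parts. The first was the immediate early list, 1.47 above acid at 2 h. A shift from the scan day DCA had to itself acts on both times. Within that day the list fell from 2 h to 6 h, by a median of -1.31, with 29 of 29 members lower, which argues against the day as the whole source. RNA quality stays open. With the actin ratio as a covariate the median at 2 h was 0.035, with a median SE of 0.66 against 0.46 without it, so the ratio may account for it. Without DCA 2 h replicate 2, the array of highest ratio, the median was 0.92, and without replicate 1 it was 1.94. DCA 2 h replicate 1 and DCA 6 h replicate 2 had like ratios (0.61 and 0.57) and medians of 0.74 and 0.09 relative to all arrays, but single arrays exclude nothing.

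The second part was the ER chaperone list, 1.20 above acid over both times with 11 members called. It did not rest on DCA 2 h replicate 2, since 6 of the 11 still passed without that array. Scan day cannot be told apart from DCA here. The list changed by 0.63 between the DCA times within the day, but a shift common to both times would remain. RNA quality cannot be fully told apart either. With the actin ratio as a covariate the median was 1.21 and 0 members were called, because the median SE went from 0.24 to 0.47. The 4 DCA arrays all had higher ratios than the 4 acid arrays. The same ratio for GAPDH was highest in DCA replicates 2 (0.35 and 0.23 at 2 h and 6 h). In replicates 1 it was 0.05 and 0.04, against 0.05 in bile mix 2 h replicate 1 and 0.14 in bile mix 6 h. ER medians relative to all arrays were 0.49 and 1.16 in those DCA arrays, and 0.01 and -0.40 in those bile mix arrays. The median kept under the covariate gives no sign that the ratio accounts for the ER rise, but with 0 members passing RNA quality is not excluded. The GAPDH comparison rests on single arrays from different scan days and excludes nothing. Exposure to DCA itself is the biological explanation the design gives, and it stays open for both parts.

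For the whole comparison of DCA with acid, a fit with 2 groups of 4 arrays gave 23 genes for the real split, and 3 of the 35 splits gave as many, so chance is not excluded by it. The highest other split gave 340. It was the split by replicate number, which points to a structure of the samples. With the replicate block, over the 18 splits that part the numbers evenly, the real one gave 48 and the highest other 3. These 18 splits are too few for a share under 0.05. For 6 h against 2 h over the same arrays the real split gave 0 genes, so all 35 had to give as many (the highest 340). This decides nothing about chance, nor about NEDD9 and FOSB.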

How the results depend on the processing

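Alternatives chosen after seeing the data were scan day with replicate number, single scan days, the actin ratio, the replicate block without DCA 2 h replicate 2, and the replicate block with quantile normalization.

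Counts of genes in the 6 comparisons without DCA and in the interaction were 0 under each alternative, except as named below. Counts that moved were, with quantile normalization, 1 for 6 h versus 2 h over acid and DCA. With median centring they were 4 for DCA 6 h and 2 for DCA 6 h versus 2 h. Without a filter they were 10 for DCA 2 h, 5 for DCA versus acid 2 h and 1 for 6 h versus 2 h over both. With the median over probe sets they were 10 for DCA 2 h and 0 for DCA 6 h versus 2 h. With every probe set they were 25 for DCA 2 h, 4 for DCA 6 h, 34 and 125 for DCA versus acid at 2 h and over both times, and 1 for 6 h versus 2 h over both. With a pseudocount of 1 they were 0 for DCA 2 h, 1 for DCA 6 h, 0, 1 and 16 for DCA versus acid at 2 h, 6 h and both, 0 for DCA versus bile mix and 0 for DCA 6 h versus 2 h. A pseudocount of 64 gave 18 for DCA versus acid 6 h and 1 for 6 h versus 2 h over both. With only the groups compared, which leaves fewer arrays to estimate the spread, they were 1 for DCA 2 h, 2 for DCA 6 h, 1 and 40 for DCA versus acid at 2 h and both, 0 for DCA versus bile mix, 0 for DCA 6 h versus 2 h and 1 for 6 h versus 2 h over both. Trend and robust moderation gave 22 and 17 for DCA versus acid at 2 h and 6 h and 2 for DCA 6 h versus 2 h. Scan day as a block gave 1 for 6 h versus 2 h over both. It could not be fitted for DCA against other groups. Unless a reason is given, the cause was not tested.

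In the order DCA 2 h, DCA 6 h, DCA versus acid 2 h, DCA versus bile mix 2 h, DCA versus acid 6 h and both times, DCA 6 h versus 2 h, and 6 h versus 2 h over both, the replicate block gave 80, 37, 105, 57, 46, 209, 38 and 18 genes, and 66, 33, 90, 51, 37, 172, 19 and 20 with quantile normalization too. It ended no call of a named gene or list, and 24 results of named genes passed only with it. Without DCA 2 h replicate 2 the block gave 5, 33, 7, 6, 38, 90, 2 and 3. The actin ratio gave 0, 5, 0, 0, 0, 0, 0 and 0. Scan day and replicate blocks gave 5 for DCA 6 h versus 2 h and 9 for 6 h versus 2 h over both. Within scan day 1 there were 0 for DCA 6 h versus 2 h, and within scan day 2 there was 1 for bile mix 2 h, where the exposed group is a single array.

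Leaving out 1 array gave 0 to 156 genes for DCA 2 h, 0 to 10 for DCA 6 h, 0 to 197 for DCA versus acid 2 h, 0 to 126 for DCA versus bile mix 2 h, 0 to 13 for DCA versus acid 6 h, 12 to 169 over both times, 0 to 121 for DCA 6 h versus 2 h, 1 to 13 for 6 h versus 2 h over both and 0 to 8 for the interaction. A group left with 1 array was assumed to vary like the others.

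The pairwise counts over 1.5-fold were 66 and 114 for acid 2 h and 6 h, 51 and 886 for bile mix, and 429 and 331 for DCA. Over 3-fold they were 0, 1, 1, 7, 26 and 14.

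Lists that reversed were, with scan day as a block, heat shock (-0.051) and G1/S (-1.15) in acid 6 h, where the day term takes up the numbers of bile mix 2 h. With quantile normalization, and with the replicate block too, it was ribosomal proteins in DCA versus acid over both times (-0.047). With scan day and replicate blocks it was immediate early in acid 6 h (0.13). With the actin ratio they were immediate early in acid 6 h (0.16), DCA versus acid 6 h (-0.46) and both times (-0.23), heat shock in DCA 2 h (-0.20) and in DCA versus acid 2 h (-0.55), bile mix 2 h (-0.18) and acid over both times (-0.48), and inflammatory genes in DCA versus acid 6 h (-0.20) and 6 h versus 2 h over both (0.10). The immediate early list in DCA versus acid 2 h reversed in the test only, with a median of 0.035. Leaving out 1 array, which makes the numbers uneven, gave -0.24 to 1.41 (G1/S) and -1.80 to 0.52 (G2/M) in acid 6 h, -1.93 to 0.26 (G2/M) in DCA 6 h, -1.26 to 0.51 (G1/S) in DCA versus acid 2 h and -0.17 to 0.77 (G1/S) in 6 h versus 2 h over both. In acid 6 h versus 2 h it gave -0.89 to 0.17 (integrated stress response), -0.42 to 1.34 (G1/S), -1.81 to 0.49 (G2/M) and -0.49 to 0.083 (cholesterol synthesis). Medians that changed sign with the call lost were as follows. For integrated stress response they were DCA 2 h (-0.47 without DCA 2 h replicate 1, -0.32 without control replicate 2), DCA 6 h (-0.13 without control replicate 2), DCA versus acid 2 h (-0.47 without DCA 2 h replicate 1, -0.35 without acid 2 h replicate 2) and DCA versus bile mix 2 h (-0.52 without DCA 2 h replicate 1, -0.50 without bile mix 2 h replicate 2). For heat shock they were DCA 2 h (-0.017) and DCA versus bile mix 2 h (-0.096), both without DCA 2 h replicate 2. The others were G2/M in DCA 6 h (0.16 without control replicate 2), TGF-beta in DCA versus acid 6 h (0.12 without DCA 6 h replicate 2), G1/S in acid 6 h (-0.0025 with scan day and replicate blocks) and inflammatory genes in 6 h versus 2 h over both (0.018 with the replicate block, without DCA 2 h replicate 2). With median centring integrated stress response in DCA versus bile mix 2 h was -0.085 with the call kept.

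Of 1923 alternative values for the 71 called results of named genes, 1220 kept the call, 703 lost it and 0 reversed. Of 2278 for the 81 list results, 1914 kept it, 336 lost it and 28 reversed in the direction of the camera test. The median changed sign in 27 of the 28, in 13 that lost the call and in 1 that kept it. The estimated correlation ended all 81. The array signal limits dim genes such as KRT20 and MUC5AC.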

Other observations

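Tests chosen only after the result was seen were those of scan day and dividing cells on the G2/M list, both tests of the G2/M level at 6 h, and the test of nutrients. Those of array scaling and of swapped numbers were chosen before.

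The arrays numbered 2 differed from those numbered 1 in 1971 genes over the 6 groups with both (936 higher, 1035 lower; limma, group means with the number as a term, adjusted p under 0.05). Counting only genes past that threshold, all 28 G2/M genes were higher in number 2 (median 1.86, adjusted p = 2.1e-37, camera; adjusted p = 0.13 with an estimated correlation). So were 24 of 27 G1/S genes (median 1.39) and 13 of 25 interferon-stimulated genes (median 0.60). RRM2 (2.77), HJURP (2.45), SPC25 (2.39) and PLK1 (2.38) were higher. CLGN (-3.50), AGR2 (-3.06), ASNS (-2.84), ASS1 (-2.31) and TRIB3 (-2.21) were lower. Of 29 integrated stress response genes, 13 were lower and 1 higher past the threshold (median -0.60, adjusted p = 1e-05, camera; adjusted p = 0.44 with an estimated correlation). Swapping the numbers within groups gave as many genes in 1 of 32 ways, the labelled one, and 5 at most in the others. This is the smallest share that 32 ways allow, so chance is unlikely but not excluded.

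Scan day does not account for the G2/M difference. In 5 of 5 groups with both arrays on 1 day the median difference was over 0.5, from 1.27 to 2.20. Array scaling does not either, since the median was 1.86 with quantile normalization and as deposited. A candidate explanation is a higher share of dividing cells in the cultures numbered 2, since both the G2/M and the G1/S list were higher in number 2 in 6 of 6 groups. No cell counts were used here.

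The G2/M list was lower at 6 h than at 2 h in 5 of 5 pairs of arrays of 1 exposure and number (acid -0.92 and -0.37, DCA -1.04 and -0.20, bile mix -1.01). Time since the medium change may account for it and cannot be told apart from exposure, because no 6 h control was used here. The number of the bile mix 6 h array does not account for all of its low level. It was -0.83 from control 1, where the other exposed arrays numbered 1 at 2 h lay between 0.06 and 0.16.

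A hypothesis from these data is that cells numbered 1 were short of nutrients before the medium was replaced, which would raise amino acid response genes and then let them fall. In acid the integrated stress response list changed from 2 h to 6 h by -0.73 in number 1 and 0.02 in number 2. In DCA it changed by -0.39 and 0.63, and in bile mix number 1 by -0.87. The falls in number 1 and the acid value in number 2 go with the hypothesis, which may be one of several. It does not account for the rise in DCA number 2.

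HMOX1 was higher than in the control of the same number in each exposed array. At 2 h the ratio was 27.2 and 4.34 in acid, 34.1 and 10.4 in bile mix, and 66.2 and 54.0 in DCA. At 6 h it was 1.95 and 1.43 in acid, 2.39 in bile mix, and 8.42 and 77.7 in DCA.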
